A study of Homo sapiens with 2 samples.

How the data were processed

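RNA-seq of 2 HaCaT libraries was examined, 1 from a dish transfected with the MigR1 vector (vector control) and 1 from a dish transfected with MigR1 carrying FLI1 (FLI1 overexpression). Groups were taken from the genotype labels. Per the labels' protocols, total RNA was sequenced on a BGISEQ instrument, and the reference was GRCh38.p13 per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here. The same protocols also mention A431 cells, which are not analysed here.

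Both deposited tables cover the whole series. The gene table lists 15159 genes by NCBI gene ID and symbol, and the transcript table lists 61479 transcripts of the same genes. Per the file headers, each holds a read count, an FPKM and a TPM per library. The deposited read counts are estimated counts that need not be whole: 84.1% of the genes of the vector control and 84.5% of the FLI1 library were whole to within 0.005 reads. The deposited FPKM values are scaled by the authors for length and depth, and were used for levels and as an alternative scale. The deposited TPM values were not used. All columns with values per library were matched to a sample. The design had foreseen raw counts, so the estimated counts were rounded to whole numbers first.

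Libraries were scaled by TMM in edgeR 4.0.16 under R 4.3.3 (factors 1.01 for the vector control and 0.991 for the FLI1 library). The log2 ratio of a gene is that of the rounded count plus 0.5, divided by the effective library size, FLI1 over vector control. A 95% interval was computed as an exact conditional (Clopper-Pearson) interval from both counts. It covers counting error only, since reads without molecular identifiers are not independent molecules, and for genes with fractional counts it leaves out the error of assigning reads. With 20 reads in each library its half-width was 0.97 on the log2 scale, with 100 reads 0.41 and with 1000 reads 0.13. Where 1 library had 0 reads the ratio is given as a bound against a floor of 3 reads in that library, which leaves out the counting error of the other library, so the lower limit of the interval can be smaller. No p-value was computed, because each group had 1 library.

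Genes with at least 20 reads in at least 1 library passed the filter. A gene was counted as at least 2-fold higher or lower at a log2 ratio of at least 1 or at most -1, a rule of size. For comparison, 1000 pairs of libraries with no difference were drawn from Poisson distributions at the pooled means. For 39 gene lists, fixed before the data were examined, the median log2 ratio was taken over members past the filter where there were at least 5 (33 lists), and set against 10000 random lists of the same size matched on mean expression in 10 bins. The lists cover inflammation, interferon responses, keratinocyte states, FLI1 targets, growth factors, stress, cell cycle, metabolism, housekeeping and other cell types. Counting error of a median came from 1000 Poisson draws. Some genes are in more than 1 list.

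The genes named were chosen by a rule fixed before the data were examined: FLI1; the 12 highest and 12 lowest genes past the filter and the size rule, ranked by the interval bound nearest to 0 and leaving out genes without an official symbol; and from each list up to 4 members past both rules, largest ratio first, or else the 2 with the highest mean expression. Genes named outside this rule are said to be so, and a near-copy is named beside the gene it shares reads with. A few genes that the rule selects are not reported here.

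Positions, GC content and transcript length came from GENCODE release 29 (GRCh38), which had a value for 98.9% of the genes. Of the 75-base words in each gene's protein-coding transcripts, a fixed sample of 1 in 8 was looked up in the protein-coding transcripts of all other genes. Only the sense sequence was used, so words shared with pseudogenes, non-coding genes or antisense overlaps were not seen. A gene was counted as sharing reads if its counts were not whole in either library, or if at least 20% of its words recurred in another gene. A gene without a value for this share was counted with them. Genes that shared at least 20% of the words of the smaller gene are called near-copies or readthrough partners. Words held by a large number of genes were left out of this pairing. Genes without a value could have no partner, so some partners can have been missed. Both definitions were made after the data had been examined.

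The calculation was tested on counts drawn for this comparison from Poisson distributions, the model that the interval assumes. This checks the calculation only, and leaves out variation between dishes and the error of assigning reads. The 95% interval held the true value for 95.3% of 11622 genes. Of 100 genes set to differ 2-fold, 96.0% had an interval on the correct side of 0 and 51.0% passed the size rule, and of 100 genes set to differ 4-fold, 100% did both. Of 11422 unchanged genes, 15 passed the size rule.

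Alternatives fixed in advance were scaling by library total or by DESeq2 1.42.0 size factors, log2 of FPKM with 0.5, 0.1 or 1 added, a pseudocount of 5 reads, no filter, a minimum of 100 reads, a minimum FPKM of 5 with FPKM + 0.5, a 1.5-fold size rule, an interval bound beyond 2-fold, and the transcript table summed per gene. Leaving out genes that share reads, and removing lowess trends (span 0.3) with GC content and length, were added after the data had been examined. Other steps used Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.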

Results

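RNA-seq values were examined for 2 libraries of HaCaT, a human epidermal keratinocyte line that became immortal spontaneously in culture. One dish received the empty MigR1 vector and 1 dish received MigR1 carrying FLI1, an ETS-family transcription factor best known from endothelium and megakaryocytes, and RNA was taken 2 days after lipid transfection. The gene table lists 15159 genes. The vector control library held 14497105 reads and the FLI1 library 14677273 reads after each gene's estimated count was rounded. With 1 library per group no difference below has a replicate check. The 95% intervals compare these 2 libraries, not the conditions, and cover counting error only.

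The series asks how FLI1 in keratinocytes relates to inflammatory genes of psoriasis, so FLI1 itself was read first. FLI1 (gene ID 2313) had 64 reads in the vector control library and 2452 in the FLI1 library. This is a log2 ratio of 5.26 (95% counting interval 4.91 to 5.65), or 38.2-fold. Its deposited FPKM was 1.60 in the control and 53.56 in the FLI1 library, which moved its rank by FPKM from 10419 to 1708. In GRCh38, the gene lies on the plus strand of chromosome 11 from 128686535 to 128813267. Among the 18 measured genes of the ETS family list, FLI1 alone was at least 2-fold higher, and the list median was 0.07. FLI1 made up 0.0167% of the reads of its library. Whether the vector holds the human or another coding sequence is not given in the labels. Summing the transcript table over each gene gave the counts of the gene table to within 0.05 reads.

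Genes at least 2-fold higher in the FLI1 library outnumbered those at least 2-fold lower, while genes with an interval above 0 (1923) and below 0 (1718) were nearer in number. Besides FLI1, the leading higher genes without shared reads were SERPINA3, an acute-phase protease inhibitor, PMEL, a melanosome protein, and SLC6A12, a betaine and GABA transporter. SERPINA3 had 0 reads in the control and 36 in the FLI1 library, at least 12.1-fold higher against a floor of 3 reads, and the lower limit of its counting interval was 9.32-fold. PMEL had 3 and 97 reads (log2 ratio 4.81, interval 3.43 to 7.33) and SLC6A12 had 1 and 41 reads (4.80, 2.81 to 10.70). The span of PMEL contains CDK2 on the opposite strand (1153 and 1015 reads, named outside the rule). The word search could not see this overlap, and the strand setting is not given. HBA1, an alpha globin gene, had 0 and 51 reads, at least 17.1-fold higher against that floor (lower limit of the interval 13.4-fold), and its near-copy HBA2 had 2 and 0. The macrophage chemokine genes CCL3L1 (41.3 and 269.3 estimated reads, log2 ratio 2.71) and CCL4L2 (6.20 and 78.4 estimated reads, 3.60) were higher as well, with counts that were not whole. P2RY11 (0 and 97.4 estimated reads), H4C11 (0 and 28), LY75-CD302 (0 and 27.99), TMEM140 (0 and 25.4) and CORO7-PAM16 (0 and 20.4) complete the 12 leading genes. These 5 all shared reads with other genes or had fractional counts, and taken alone their ratios were at least 32.5, 9.38, 9.38, 8.38 and 6.70-fold. A test of partners was chosen after values had been seen. In it, fewer reads of a partner offset those of H4C11 (its near-copy H4C12 had 31 and 0) and LY75-CD302 (LY75 had 60 and 22). The outcome was undecided for CORO7-PAM16 (its partners had 418 and 398). It was also labelled undecided for P2RY11, because its partner PPAN-P2RY11 (409 and 171) lost more reads than P2RY11 gained. Of 11659 genes with at least 20 reads in 1 of the libraries, 139 were at least 2-fold higher, 56 were at least 2-fold lower and 98.3% were neither. In 1000 simulated pairs of libraries that differed by Poisson counting alone, the mean was 11.7 higher and 12.8 lower genes and the highest was 24 in either direction. At a minimum of 100 reads the counts were 49 higher and 7 lower, and from FPKM with 0.5 added they were 66 and 10.

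**Figure D1:**
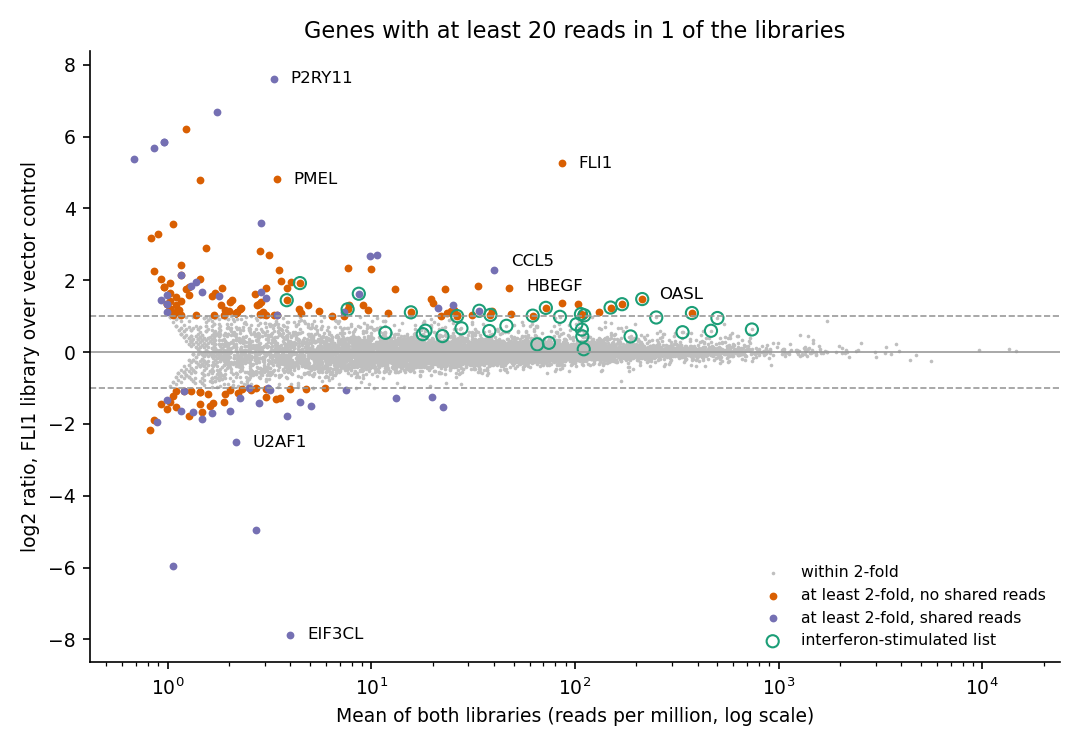
Each point is 1 of 11659 genes, with the mean of both libraries in CPM on a log axis against the log2 ratio of the FLI1 library over the vector control; dashed lines mark 2-fold. FLI1 lies at 5.26, all 36 interferon-stimulated genes (circles) lie above 0, and the lowest points, such as EIF3CL, share reads with other genes; the position of a gene with 0 reads in 1 library depends on the 0.5 reads added.

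The 12 leading genes on the lower side all shared reads with another gene or had counts that were not whole. EIF3CL, a near-copy of the translation initiation factor gene EIF3C, had 117.4 estimated reads in the control and 0 in the FLI1 library, at least 38.8-fold lower. EIF3C itself had 6617 and 6306. The histone gene H4C12 had 31 and 0 reads, at least 10.3-fold lower, while its near-copy H4C11 had 0 and 28. The splicing factor gene U2AF1 (log2 ratio -2.51) and the protocadherins PCDHGC4 (-4.95) and PCDHGB7 (-1.85) belong to families of near-copies or of genes with common exons. ARPIN-AP3S2 (-1.79), PPAN-P2RY11 (-1.25), BUB1B-PAK6 (-1.27) and C8orf44-SGK3 (-1.38) are readthrough loci. NPIPA3 (-1.50), GPRASP2 (-1.64) and the cytochrome gene CYP3A5 (-1.70) complete the group. Genes with shared reads made up 42.9% of the 56 lower genes, 19.4% of the 139 higher genes and 20.9% of all genes past the filter. Without them 32 genes were at least 2-fold lower, and 0 of these had an interval wholly beyond 2-fold, against 33 of the 112 higher ones.

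Inflammatory genes of the kind raised in psoriatic skin were more often higher than lower in the FLI1 library, while for the S100 alarmins no difference was detectable at this depth. The chemokine genes CCL5 (198.8 and 970.6 estimated reads, log2 ratio 2.29, interval 2.07 to 2.52) and CCL22 (1.10, 0.77 to 1.44) and the interleukin-1 genes IL1A (1.14, 0.92 to 1.38) and IL1B (1.05, 0.89 to 1.22) were each more than 2-fold higher. PI3, which encodes the elastase inhibitor elafin, had 707 and 1798 reads (1.35, 1.23 to 1.48). Among inflammatory cytokines, 14 of 16 measured genes had a ratio above 0, 11 with an interval above 0, and the median was 0.65, or 0.35 from FPKM with 1 added. For chemokines these numbers were 5 of 8, 5 and 0.44. The cytokine list also holds the receptor antagonist genes IL1RN (0.41) and IL36RN (0.73), outside the naming rule, each with an interval above 0. In the NF-kB list, 20 of 22 genes had a ratio above 0, 12 with an interval above 0 and 1 below it, and the median was 0.31, or 0.19 from FPKM with 0.5 added and a minimum FPKM of 5. TRAF1 (1.94), TNFAIP3 (1.12) and IRAK2 (1.09), all members of NF-kB signalling, were at least 2-fold higher. TNFAIP3 is an inhibitor of that signalling, so the list counts activators and inhibitors alike. In the antimicrobial and alarmin list, 8 of 11 genes had a ratio above 0, 5 with an interval above 0, and the median was 0.26. The IL-17 and IL-23 list had a median of 0.12, and 10 of its 13 intervals included 0. STAT3 (0.12) and TRAF3IP2 (0.04), its members with the highest expression, differed by less than 1.5-fold. Medians of the cytokine, chemokine and NF-kB lists lay above those of all 10000 random lists of matched expression, and the alarmin and IL-17 medians lay at percentiles 99.8 and 98.1.

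Several psoriasis genes outside the naming rule were looked up after values had been seen. CXCL8 (0.78, interval 0.66 to 0.90), IL23A (0.97, 0.43 to 1.53), IL36G (0.85), IL6 (0.74, 0.17 to 1.35) and NFKBIZ (0.78) were higher in the FLI1 library. S100A8 had 21 and 14 reads, S100A9 95 and 93, S100A7 14 and 13, LCN2 198 and 220, TNF 7 and 14, and CCL20 1 and 1, and all 6 intervals included 0. Over the 5 inflammatory lists, 68 distinct genes were measured: 34 had an interval above 0, 1 below 0 and 33 including 0. Of these 68 genes, 8 were at least 2-fold higher and 0 at least 2-fold lower.

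**Figure D2:**
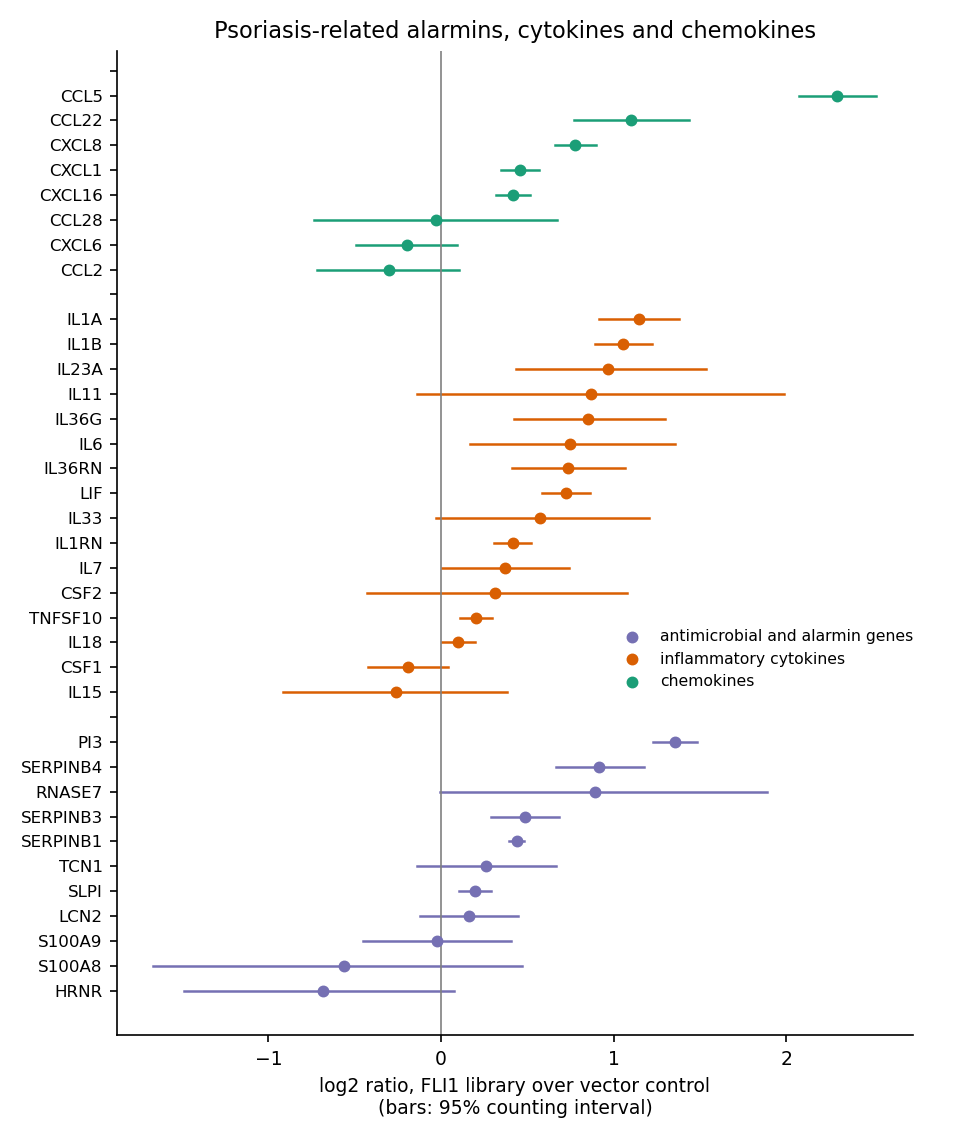
Log2 ratio of the FLI1 library over the vector control for each measured gene of the alarmin, cytokine and chemokine lists, with bars for the 95% counting interval of 1 library per group. CCL5 lies highest at 2.29, and the intervals of S100A8, S100A9 and LCN2 include 0.

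Interferon-stimulated genes were higher as a list. All 36 measured members had a higher value in the FLI1 library, 35 of them with an interval above 0, and 16 were at least 2-fold higher. The antiviral GTPase genes MX2 (log2 ratio 1.92, interval 1.32 to 2.61) and MX1 (1.62, 1.21 to 2.07), the oligoadenylate synthetase-like gene OASL (1.48, 1.39 to 1.56) and IFI44L (1.44, 0.84 to 2.11) had the largest ratios. The list median was 0.95 (0.76 from FPKM with 0.5 added and a minimum FPKM of 5), above all 10000 random lists, whose middle 95% of medians ran from -0.05 to 0.06. IFIH1, a cytosolic RNA sensor, was 2.08-fold higher. The 12 measured nucleic acid sensors had a median of 0.08, which was 0.23 without genes that share reads, and 5 of them had an interval above 0 and 1 below it. Interferon genes themselves were near the detection limit, and 1 of them, IFNE (22 and 21 reads), passed the filter. Antigen presentation genes had a median of 0.03 (0.14 without genes that share reads), with B2M at 0.13.

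Keratinocyte differentiation genes differed in both directions. The cornified envelope genes CNFN (2 and 24 reads, log2 ratio 3.30, interval 1.58 to 6.72), SBSN (10 and 73 reads, 2.82, 1.92 to 4.00) and SPRR2A (1.66) were higher in the FLI1 library, and the suprabasal keratin KRT77 was lower (29 and 8 reads, -1.79, -3.19 to -0.69). KRT1 (-1.28, -1.96 to -0.66) and KRT10 (-0.28), the keratin pair of the spinous layer, were lower too, and IVL had an interval that included 0; these 3 genes were picked after values had been seen. Of 23 measured differentiation genes, 13 had an interval above 0 and 4 below it, and the median was 0.29, or 0.0841 from FPKM with 0.5 added and no filter. Basal keratinocyte genes had a median of 0.06 (0.0038 from FPKM with 0.5 added and no filter), with KRT5 at -0.26 and KRT14 at -0.05. The 4 measured keratins of activated epidermis, fewer than the 5 needed for a median, all had an interval above 0. Of these, KRT6B alone was at least 2-fold higher (1.32), from reads shared with its near-copies KRT6A and KRT6C, and the other 3 had ratios from 0.23 to 0.44. The simple epithelial keratins KRT18 (0.32) and KRT8 (0.24) were slightly higher, and KRT19 (-0.19) and KRT80 (-0.28), named outside the rule, were slightly lower. The list had 2 intervals above 0, 2 below it and 2 that included it, and the median was 0.13.

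Few of the genes tied to FLI1 in endothelium had enough reads to be measured. ROBO4, an endothelial guidance receptor, had 37 and 187 reads (log2 ratio 2.33, interval 1.83 to 2.90). NOS3, endothelial nitric oxide synthase (1.07, 0.41 to 1.79), and EGFL7 (1.03, 0.15 to 2.01) were about 2-fold higher. All 5 measured endothelial targets had a ratio above 0, 4 with an interval above 0 and 3 at least 2-fold higher, and the median was 1.03. The other 11 of the 16 listed in the table had fewer than 20 reads in both libraries and intervals that included 0. With every gene that had a read included, the median was 0.40, and 0.0673 from FPKM with 0.5 added. Megakaryocyte and blood cell targets had a median of 0.20, with the platelet receptor gene GP1BA at 1.02, and at a minimum of 100 reads the median was 0.0044. The 16 measured EWS-FLI1 targets had a median of -0.11, 7 with an interval below 0 and 3 above it, and CCND1 (0.08) and CAV1 (-0.07) were their most abundant members.

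Immediate early genes were mostly higher, and genes of the growth factor lists were more often higher than lower, with a few lower. HBEGF, a ligand of the epidermal growth factor receptor, had 315 and 1071 reads (1.77, 1.59 to 1.96). The 10 measured genes of its list, which also holds receptor genes, had a median of 0.31. Of these, 6 had an interval above 0 and 2 below it, the ligand gene EPGN and the receptor gene ERBB2 (named outside the rule). VEGFC was 2.00-fold higher in an angiogenic list of 13 measured genes with a median of 0.41, 9 with an interval above 0 and 1 below it. The transcription factor genes EGR3 (2 and 22 reads, 3.18, 1.44 to 6.60), ATF3 (1.32), FOSB (1.30) and EGR1 (1.13) led the immediate early list, in which 17 of 22 genes had an interval above 0 and 1 below it, and the median was 0.66. Heme oxygenase HMOX1 (154 and 520 reads, 1.76) was higher among oxidative stress genes with a median of 0.19.

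Mitotic genes were slightly and uniformly lower. All 27 genes of the G2 and M phase list had a ratio below 0, 26 with an interval below 0, and the median was -0.24. MKI67 (-0.25, -0.29 to -0.21) and TPX2 (-0.22) were its most abundant members. S phase genes had a median of -0.12, with 13 of 27 intervals below 0, and MCM7 (-0.17) and PCNA (-0.14) were among them. Both medians lay below those of all 10000 random lists. Replication-dependent histones had a median of 0.36 in 12 genes, of which 3 had an interval above 0 and 9 an interval that included it. H4C3 had 8 and 28 reads (1.75, 0.64 to 3.16). The cell cycle inhibitor CDKN1A was 1.61-fold higher, while p53 targets as a list had a median of 0.05, with PERP at 0.04.

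**Figure D3:**
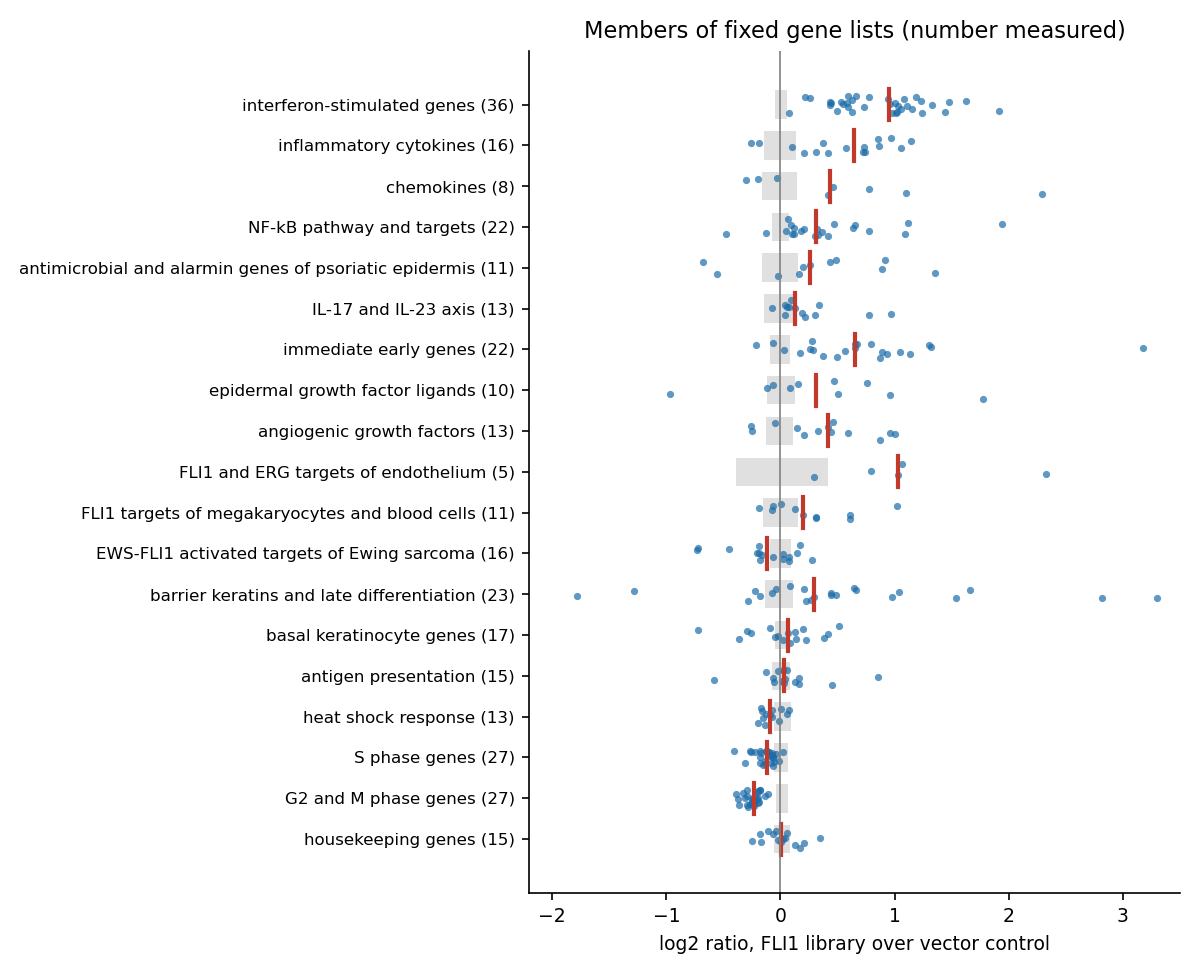
Log2 ratio of the FLI1 library over the vector control for each measured member (points) of 19 gene lists, with the list median (red line) and the middle 95% of medians of 10000 random lists of matched expression (grey). The interferon-stimulated median lies at 0.95 and the G2 and M phase median at -0.24; FLI1 is in none of the lists drawn.

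The remaining lists had medians between -0.09 and 0.17. Matrix and collagen genes had a median of 0.05, with CCN2 (1.77) among the genes at least 2-fold higher, and this median changed sign under 4 other settings. MMP9 (8 and 29 reads, 1.80) stood out among matrix metalloproteinases, whose median was 0.06. Epithelial to mesenchymal transition genes had a median of 0.17, above the middle 95% of random lists (-0.07 to 0.09), with 11 of 16 intervals above 0 and 1 below it. The list mixes epithelial and mesenchymal genes, so these numbers give no direction of a transition. Its most abundant members were the epithelial genes CDH1 at 0.12 and CLDN7 at 0.01, the latter below 0 when scaled by library total, and the integrin gene ITGA5, picked after values had been seen, was at 0.98 (0.88 to 1.08). Apoptosis regulators had a median of 0.13, with PMAIP1 at 0.78 and MCL1 at 0.29, and inflammasome genes 0.15. Both medians lay above the middle 95% of random lists, whose upper limits were 0.08 and 0.14. Of their intervals, 13 of 20 and 10 of 13 included 0. The unfolded protein and integrated stress list had a median of 0.04, and hypoxia and glycolysis 0.06, with PKM at 0.13 and GAPDH at -0.04. Heat shock genes had a median of -0.09, with HSPA8 at -0.07 and HSP90AA1 at -0.13. This median lay below the middle 95% of random lists (-0.05 to 0.09), with 9 of 13 intervals below 0 and 1 above it. Cholesterol synthesis genes had a median of -0.04, with HMGCS1 at -0.01. Housekeeping genes had a median of 0.0019, which lay below 0 under both other scalings, and ACTB (0.02) was below 0 when scaled by library total.

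Markers of other skin cells were few. Of the fibroblast list COL1A1 alone passed the filter (100 and 98 reads, -0.02). Of the leukocyte list CD68 (0.63, 0.40 to 0.87) and ITGAM (0.60, -0.22 to 1.48) passed, and CD68 is also made by cells other than leukocytes. Of the melanocyte list PMEL and MITF passed. The other 4 listed melanocyte genes, MLANA, TYRP1, DCT and MITF, together had 63 and 79 reads, a ratio of 1.26 (0.894 to 1.78). MITF alone had 56 and 72 of these reads. MLANA had 4.56 and 5 estimated reads, TYRP1 0 and 2, and DCT 2 and 0, all below the filter. The sum thus rests mainly on MITF and cannot tell whether MLANA, TYRP1 and DCT differed as PMEL did. None of the 26 mitochondrially encoded genes is in the table.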

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

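The look at single FLI1 transcripts was chosen only after the reads of the gene had been seen. The transcript table splits the reads of FLI1 among its annotated transcripts, which no comparison above used, and 2 of them lay above the vector control beyond counting error. XM_011542702 had 1418.09 estimated reads in the FLI1 library and 4.09 in the vector control. NM_002017, the reference transcript, had 1032.78 and 11.61. XM_017017405, which held most FLI1 reads of the control (48.31), had 0 estimated reads in the FLI1 library, and NM_001271010 had 1.13 and 0. The split between transcripts with common exons is an estimate by the authors' software, and no explanation for it was tested.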

How the results depend on the processing

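Leaving out genes that share reads and removing trends with GC content and length were chosen only after the data had been seen, and all other alternatives were planned. No paired analysis was possible because each group had 1 library, and there was likewise no spare library of a group to leave out. Of the list medians recomputed under the alternatives, 400 stayed inside the counting interval of the reported value and 22 moved outside it. Another 4, all of 1 list, changed sign. For single named genes these numbers were 909, 120 and 3. A change of sign was counted as such only where the counting interval of the reported value excluded 0. Other values that crossed 0 are among those that stayed or moved. The cause was not tested unless stated.

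The FLI1 log2 ratio was 4.69 from FPKM with 0.5 added and 4.39 with 1 added, a larger constant that pulls low values together by construction. Genes at least 2-fold higher and lower numbered 66 and 10 with FPKM + 0.5, 50 and 7 with FPKM + 1, 1178 and 847 with no filter on low counts, 49 and 7 at a minimum of 100 reads, and 41 and 6 with FPKM + 0.5 and a minimum FPKM of 5. With a pseudocount of 5 reads 34 were lower, with FPKM + 0.5 and no filter 28 were lower, and without genes that share reads 32 were lower. With the interval bound beyond 2-fold they numbered 45 and 6, and with a 1.5-fold rule 409 and 244.

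Scaled by library total, the medians of hypoxia and housekeeping genes were 0.0310 and -0.0237, and ACTB was -0.0030. The median of matrix and collagen genes changed sign to -0.0027 with FPKM + 0.5, -0.0042 with FPKM + 0.1, -0.0021 at 100 reads and -0.0044 with FPKM + 0.5 and a minimum FPKM of 5. With FPKM + 0.5 the hypoxia median was 0.0340. With FPKM + 1 the medians were 0.35 for cytokines, 0.82 for interferon-stimulated genes, 0.46 for endothelial targets, 0.53 for immediate early genes and 0.0305 for hypoxia. With no filter, the list of epidermal growth factor ligands and receptors had 0.47 and endothelial targets 0.40. At 100 reads, megakaryocyte targets had 0.0044. With FPKM + 0.5 and no filter the medians were 0.36 for cytokines, 0.0841 for late differentiation, 0.0038 for basal keratinocyte genes, 0.0673 for endothelial targets and 0.13 for epithelial to mesenchymal transition. With FPKM + 0.5 and a minimum FPKM of 5 they were 0.19 for NF-kB and 0.76 for interferon-stimulated genes. Without genes that share reads they were 0.14 for antigen presentation, -0.0700 for heat shock and 0.23 for nucleic acid sensors. The median of simple epithelial keratins, whose counting interval includes 0, was -0.0085 with FPKM + 0.1. With trends removed, simple epithelial keratins had 0.18, KRT14 0.0018 and GAPDH 0.0041. Depth limits genes near 20 reads, where an interval spans 0.97 on either side.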

Other observations

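All tests of explanations in this part were chosen only after the results had been seen, and so were the genes of the next paragraph. Several further genes without shared reads were at least 2-fold higher or lower. DLL4, a Notch ligand of endothelium, had 2 and 29 reads in the control and FLI1 libraries (log2 ratio 3.57, interval 1.88 to 6.98). CEACAM1, an adhesion receptor, had 49 and 242 (2.30), the protease ADAMTS9 5 and 40 (2.89), and the chemokine gene CCL3 12 and 80 (2.69, 1.86 to 3.76). IGFL1, of the insulin growth factor-like family, had 212 and 761 (1.85). PRDM1, a repressor of transcription, had 17 and 85 (2.30), ISG20, an interferon-induced exonuclease, 87 and 294 (1.76), and HAS2, a hyaluronan synthase, 152 and 421 (1.47). On the lower side PTGIS, prostacyclin synthase, had 20 and 4 reads (-2.18, -4.32 to -0.74), ZCCHC18 71 and 28 (-1.32), METTL7A 63 and 26 (-1.25), and MYLK, myosin light chain kinase, 116 and 57 (-1.01). No lower gene without shared reads had an interval wholly beyond 2-fold. Of the 139 genes at least 2-fold higher, 91 are in no fixed list, and 16 are in the interferon-stimulated list.

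All 36 measured interferon-stimulated genes had a ratio above 0, 35 with an interval above 0 and 16 at least 2-fold higher. A scaling or depth error shifts random lists alike, and the list median lay 0.90 above their upper 95% limit. Removing trends with GC content and length left a median of 0.956, which argues against these biases as the whole cause. More interferon transcripts may contribute, since the summed reads of 6 listed interferon genes were 26 and 45 (log2 ratio 0.79, interval 0.07 to 1.55), and 4 and 24 without IFNE. With 1 dish per group, an effect of FLI1 and a difference between the 2 dishes that is not due to FLI1, such as the amount of plasmid, cannot be told apart.

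The G2 and M phase list was slightly lower in the FLI1 library. Its median lay beyond the lower 95% limit of random lists by -0.19, so a scaling error, which moves both alike, does not account for it. Without the trends of GC content and length the median was -0.23. It lay below the S phase median by a difference of -0.11, beyond the counting error of both. A smaller share of cells in G2 and M in the FLI1 dish would give this. The S phase median was itself lower (-0.12) than those of all random lists, so this comparison cannot tell such a share from fewer cycling cells. Cell numbers and phases were not measured, and 1 dish per group leaves other differences between dishes open.

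Of the 56 genes at least 2-fold lower, 24 shared reads or had counts that were not whole. The word search found a near-copy or readthrough partner for 10 of the 56. It found none for PCDHGC4, PCDHGB7 and C8orf44-SGK3, so these were not tested. Reads divided differently among near-copies or readthrough loci could lower 1 of them, and then its partners gain what it lacks. For 3 of these 10 genes the outcome was undecided. Of 7 with a decided outcome, the partners gained the missing reads for 4, among them H4C12, and not for the other 3. Among these 3, EIF3CL lacked 116 reads beside 6617 in its partner and NPIPA3 lacked 70.4 beside 1473 in its partners. There a small difference between dishes can hide a gain. The third, PPAN-P2RY11, lacked 235.8 reads beside 903 in its partners, which gained 40.9 (-43.0 to 124.8), less than it lacked. With 4 genes offset and 3 not, the test leaves open how far reads divided differently account for the lower genes. For the 32 lower genes without shared reads, counting error alone is argued against as the cause of all of them. The 1000 simulated pairs held 9.6 such genes on average and at most 19, so counting error can account for some. Variation between dishes beyond counting was not measured.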
